A study of Mus musculus with 6 samples.

How the data were processed

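Stellate ganglia, the paired sympathetic ganglia that supply most of the sympathetic nerve fibres of the heart, were taken from male C57/Bl6 mice 8 weeks after transverse aortic constriction (TAC) or a sham operation. TAC narrows the aortic arch and so raises the pressure against which the left ventricle pumps. RNA from both ganglia of 1 animal was hybridised to 1 Affymetrix GeneChip array of the mouse genome, per the labels' protocols, after a single round of 3' amplification and biotin labelling. There were 3 sham and 3 TAC arrays, each carrying a letter A, B or C in its title, and each array was treated as 1 animal.

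The deposited values are probe set intensities on a linear scale. They were made by the authors with GCRMA, per the submitters' processing notes, which corrects for probe-sequence-dependent background, normalizes between arrays and summarises the probes of a set. Its version and settings are not given in the sources used here. The table held 45101 probe sets, of which 64 were Affymetrix controls. No array stood for another: the most identical values shared by any pair of arrays was 8. The values were log2-transformed here with no pseudocount, and no further normalization was applied in the analysis as reported. GCRMA gives no detection call, so probe sets whose mean log2 intensity over all 6 arrays was under 4 were left out. This removed 27487 dim probe sets and left 17550 for testing. GCRMA compresses values near background, so a fold against a group under the floor is uncertain. For such genes the fold with the dim group set at the floor is given as well.

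The gene symbols came from GEO's annotation of the array platform. Of all probe sets, 34958 had 1 symbol, 932 had several and 9211 had none there, and no gene was named from a probe set with several symbols. Of the annotation rows with 1 symbol, 34754 matched the RefSeq gene table of mouse assembly GRCm38.p6 by gene identifier, and 0 symbols needed an update. That table was used for names only. Where a gene had several tested probe sets, the one with the highest mean over all arrays stood for it, which gave 9955 genes.

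TAC and sham arrays were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Before the data were examined, 38 gene lists were fixed, 20 of pathways and 18 of cell type markers. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over the 29 lists tested. Camera with the correlation estimated per list, and fry, were run beside it. Within each list the members were also adjusted over the list alone. This list-alone p does not account for the number of lists, so a single member that passes may do so by chance. Standard errors of log2 differences are limma's moderated ones. With 3 animals against 3, an exact permutation test of a single value cannot give a p below 0.1, and the number of arrays limits the precision.

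The genes named were set by rule before the data were examined: the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap. Places left open were filled with the genes of smallest unadjusted p among those with an absolute log2 difference of at least 0.58 and groups that did not overlap. Every member of the catecholamine list and up to 4 members of smallest p from each other list were added. Other members of the neuropeptide, heat shock, synaptic, muscle, fat and clock lists named in the text were chosen after their values were seen.

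The procedure was tested on simulated data with the means and moderated variances of the 17550 probe sets, in 20 simulations of TAC against sham with 200 probe sets changed in each. It called 35.3% of the probe sets changed by 0.58 on the log2 scale, 85.4% of those changed by 1 and 98.7% of those changed by 2. Wrongly called were 7.2 unchanged probe sets per simulation. These simulations drew probe sets independently, without shared variation between arrays. The shares called also rest on 200 planted changes per simulation and on the moderated variances taken as true. They do not give the chance of calling a lone change in the real data. There, Sst at 2.89 and Cartpt at 1.89 were not called (limma adjusted p = 0.141). A list shift of 0.5 given to the neuropeptide list was called by camera in 20 of 20 simulations over 9955 genes, with 6 calls of other lists in total. Figures were drawn with matplotlib 3.10.9, and no genome coordinates were used.

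Alternatives covered the floor (none, or a mean log2 of at least 6), the variance model, array weights, renormalization, thresholds, the treatment of several probe sets per gene, the letter of the titles as a block, and each array left out in turn. Scores of brown fat and muscle transcripts as covariates, and a comparison without sham C and TAC B, were added after the data had been seen.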

Results

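Gene expression was measured in the stellate ganglia of 3 sham-operated mice and 3 mice with transverse aortic constriction, 8 weeks after surgery, to compare sympathetic ganglia with and without lasting pressure overload of the heart. All 6 arrays correlated at 0.981 to 0.994 over the tested probe sets. The array TAC B stood furthest from the others, with a mean correlation of 0.984 and a score of 36.1 on the first principal component, which held 37.7% of the variance. The median linear intensity over all probe sets was 7.96 to 8.44 on the sham arrays and 7.81 to 7.85 on the TAC arrays.

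Transcripts of neuropeptides, granins and the enzymes that process them were called higher in TAC than in sham ganglia by camera (adjusted p = 3.27e-10), and this call was lost with an estimated correlation (adjusted p = 0.188). Of 15 measured members, 14 had a higher mean after TAC, with a median log2 difference of 0.46, or 1.38-fold. Adjusted over the list alone, 9 members rose and 0 fell. Adjusted over all probe sets tested, limma called 0 of the 15, with 9 at an unadjusted p under 0.05. Sst, which encodes the inhibitory peptide somatostatin, went from 3.56 ± 0.04 on the log2 scale in sham to 6.45 ± 0.52 in TAC (SD, n = 3). That is 7.41-fold, but the sham values lay under the floor of 4, and with sham set at the floor the fold is 5.46. Cartpt, the precursor of the CART peptides, rose from 6.64 ± 0.12 to 8.53 ± 0.30 (SD, n = 3), or 3.70-fold. Npy, the classical peptide cotransmitter of noradrenaline in sympathetic neurons, was already among the brightest transcripts at 13.77 ± 0.14 and rose to 14.53 ± 0.14 (SD, n = 3), or 1.70-fold. Galanin (Gal) rose 2.07-fold, and vasoactive intestinal peptide (Vip) 1.49-fold.

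Among the granins and processing enzymes of dense-core vesicles, 4 members rose over the list alone. Vgf, a secreted granin family protein, rose by 0.82 on the log2 scale (SE 0.23). Pcsk1, a prohormone convertase, rose by 0.81 (SE 0.22), chromogranin B (Chgb) by 0.46 (SE 0.09) and Scg5, a chaperone of a prohormone convertase, by 0.44 (SE 0.15). In all 9 members that rose, the 3 TAC arrays lay above the 3 sham arrays. The other 6 did not pass over the list alone, with log2 differences of 0.31 for Scg2, 0.21 for Cpe, 0.18 for Scg3, 0.15 for Chga, 0.14 for Calcb and -0.07 for Pcsk1n. Fry, which tests whether the members move one way on balance, called the list (adjusted p = 0.00701). Sst, Cartpt, Npy and Chgb passed over the list alone under each alternative that measured them. Gal passed in 15 of 16 alternatives, Pcsk1 in 12, Vip in 11, Vgf in 10 and Scg5 in 8. The count of 9 was 4 without sham A, 5 with the skeletal muscle score as a covariate and 5 with no floor, where the median was 0.21. On TAC B, the array furthest from the others, Pcsk1 measured 9.612, against 8.825 and 8.845 on TAC A and C. Gal, Npy, Vgf and Scg5 were also highest on TAC B, while Sst, Cartpt, Chgb and Vip were not. Without TAC B the count was 7 and the median 0.44.

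**Figure D1:**
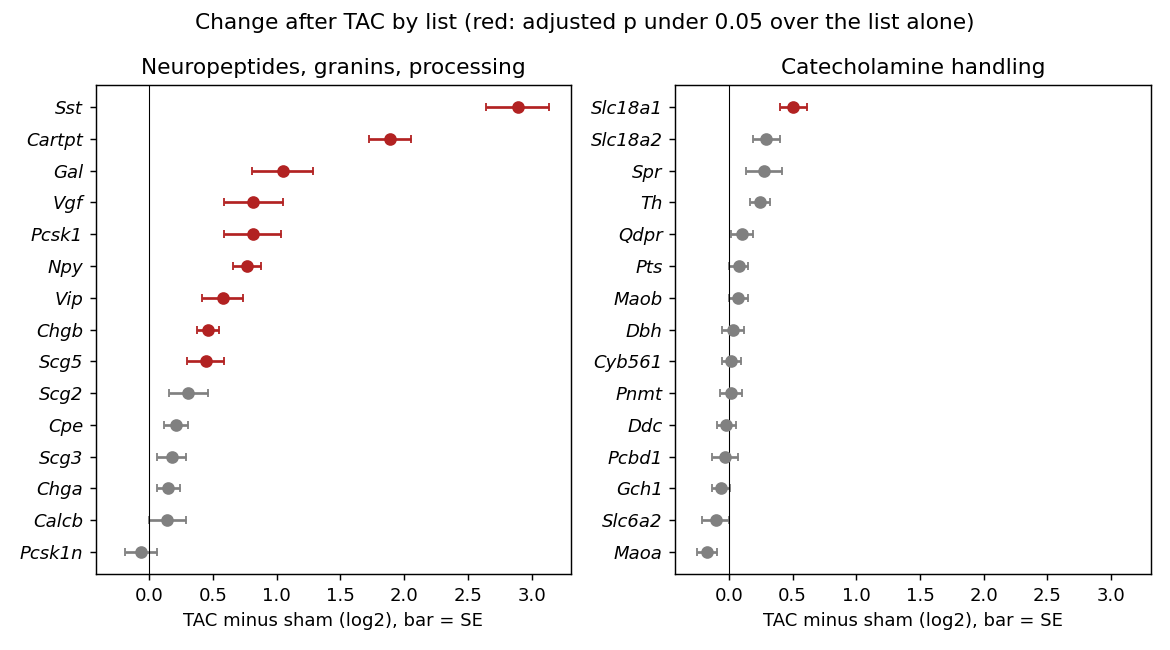
The x axis gives the TAC minus sham difference in log2 intensity for each measured member of the neuropeptide list (left) and the catecholamine list (right), with bars for the moderated SE over 3 arrays per group. Red points passed 0.05 adjusted over the list alone: 9 members on the left, led by Sst at 2.89 and Cartpt at 1.89, and Slc18a1 at 0.50 on the right.

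Among the enzymes and transporters of noradrenaline handling, 1 rose over the list alone, and the list was called by fry (adjusted p = 0.0144) and not by camera (adjusted p = 0.318). The 15 measured members of the catecholamine list had a median log2 difference of 0.03, as had all tested probe sets, and fry does not compare a list with other genes. With no floor camera called the list (adjusted p = 0.0309), though its median was then 0.025. Camera compares a list with the other genes. Of the probe sets under the floor, which then enter, 87.0% were lower on the TAC arrays. The member that rose was the vesicular monoamine transporter Slc18a1, from 6.51 ± 0.06 to 7.01 ± 0.17 (SD, n = 3), or 1.42-fold with adjusted p = 0.0367. Adjusted over all probe sets, limma called 0 members, with 3 at an unadjusted p under 0.05. Tyrosine hydroxylase (Th), the rate-limiting enzyme of catecholamine synthesis, measured 13.59 ± 0.06 in sham and 13.84 ± 0.06 in TAC (SD, n = 3), 1.18-fold, with groups that did not overlap and adjusted p = 0.138 over the list. The main neuronal vesicular transporter Slc18a2 was 0.29 higher (SE 0.11) and did not pass either. Dopamine beta-hydroxylase (Dbh) differed by 0.03 (SE 0.09), Ddc by -0.02 (SE 0.07) and the noradrenaline transporter Slc6a2 by -0.10 (SE 0.10).

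Among the remaining members, Spr differed by 0.27, Qdpr by 0.10, Pts by 0.08, Maob by 0.07, Cyb561 by 0.02 and Pnmt by 0.02. Lower means were measured for Maoa at -0.17, Gch1 at -0.06 and Pcbd1 at -0.03. Other probe sets of the same genes differed from the brightest one. For Slc6a2 they were at -0.37, with every TAC array below every sham array, and at 0.20 and 0.07. For Dbh they were at 0.12 and -0.0094, and for Gch1 at 0.28. The call of Slc18a1 was lost when any 1 of sham A, sham B, sham C, TAC A or TAC B was left out, which brought the count from 1 to 0, and it held without TAC C. It was also lost with array weights, quantile normalization, the title letter as a block, the brown fat score as a covariate and without sham C and TAC B, and so passed in 6 of 16 alternatives.

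**Figure D2:**
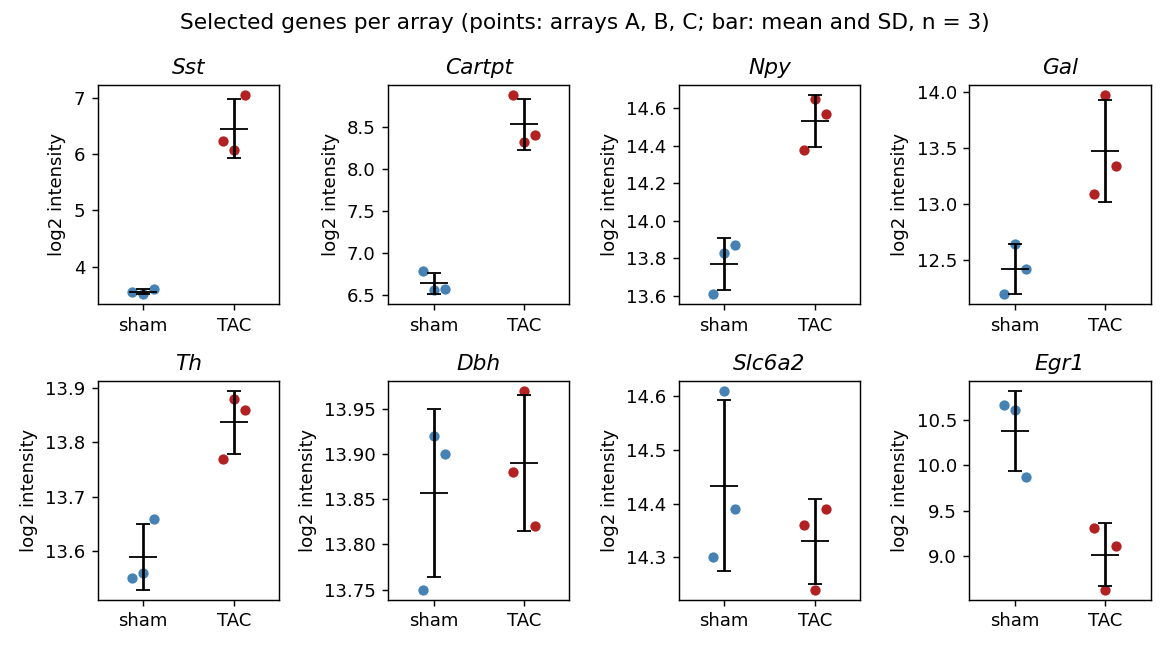
Each panel plots the log2 intensity of 1 gene on the 3 sham and 3 TAC arrays, with the group mean and SD, on its own y axis range. Sst, Cartpt, Npy, Gal and Th lay higher on every TAC array than on any sham array, Egr1 lay lower, and the groups overlapped for Dbh and Slc6a2.

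Over all 17550 probe sets, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.141, for Sst and Cartpt. At an unadjusted p under 0.05 there were 1594, against 877.5 from chance alone, 1059 of them higher and 535 lower after TAC. The groups did not overlap for 17.9% of probe sets, where chance gives 10%, with 1583 higher and 1554 lower. Without TAC C the count of calls was 1, Sst.

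The genes named by the rule were taken by unadjusted p and did not pass over all probe sets. Besides Sst, Cartpt and Npy, the higher ones were the long noncoding RNA host gene Mir670hg at 1.91, the Ras-like gene Rerg at 1.20, the kinase gene Pkn2 at 1.01, AI467606 at 0.99, the RNA polymerase subunit gene Polr3g at 0.77, AA467197 at 0.74, Fxyd5 at 0.64, Rhbdd1 at 0.61 and Lactb2 at 0.60. Sham means of Mir670hg, Pkn2 and AI467606 lay under the floor, and their folds with sham at the floor were 2.29, 1.98 and 1.79. The lower ones were led by alpha-fetoprotein (Afp), from 11.36 ± 0.59 to 9.02 ± 0.62 (SD, n = 3). Next came Egr1 at -1.37, the polysialyltransferase St8sia2 at -1.36, the retinoic acid binding protein Crabp1 at -1.29 and the matrix proteoglycan Fmod at -1.24. TAC means of St8sia2 and Fmod lay under the floor, and their folds with TAC at the floor were 1.70 and 1.91. Rgs8 was at -0.72, Ahsa2 at -0.66, endothelin 3 (Edn3) at -0.65, the presynaptic adhesion gene Nrxn3 at -0.65, Smoc2 at -0.61, Pcp4 at -0.60 and Aifm2 at -0.59.

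Camera called 4 of 29 tested lists, 2 higher and 2 lower after TAC, and 0 of them with an estimated correlation. The estimate was 0.068 for the neuropeptide list and 0.149 for the matrix list, above the preset 0.01. It was -0.037 for the heat shock list and -0.098 for the clock list, so their calls were not lost through a larger correlation. Fry called the neuropeptide, catecholamine, circadian clock and heat shock lists, and not the matrix list (adjusted p = 0.697). Besides the neuropeptides, the circadian clock list was higher, with a median of 0.27 over 10 members and adjusted p = 0.0251 (adjusted p = 0.367 with an estimated correlation). None of its members passed over the list alone, and Per3 was at 0.69, Per1 at 0.58, Cry2 at 0.51 and Cry1 at 0.28. Sham means of Per3 and Per1 lay near the floor, at 4.01 and 4.64. Per3 measured 4.17 on TAC B, against at most 4.15 on the sham arrays. Its other probe sets, all under the floor, were at -0.09 to 0.11. The clock median was 0.16 with no floor and 0.18 without sham A, and the call was lost without sham A (adjusted p = 0.126), without TAC C (adjusted p = 0.0935), with the muscle score as a covariate (adjusted p = 0.124), with a floor of 6 (adjusted p = 0.186) and with the title letter as a block (adjusted p = 0.0520). The cytosolic heat shock list was lower, with a median of -0.09 over 14 members and adjusted p = 0.0138 (adjusted p = 0.367 with an estimated correlation). Its inducible chaperone Hspa1b fell 1.48-fold (list-alone adjusted p = 0.0135), and Hsph1 at -0.52 and Dnajb1 at -0.37 did not pass. The value of Hspa1b is uncertain, since its probes may also read the near-identical Hspa1a, whose own probe set was at 0.22. The heat shock median was -0.14 without sham A and -0.06 without TAC B or with array weights. The heat shock call was lost with no floor (adjusted p = 0.411) and after quantile normalization (adjusted p = 0.0972), and that of Hspa1b without sham A, sham B, TAC A or TAC C (list-alone adjusted p = 0.0519 to 0.0715), with the mean of all probe sets and with the block, so that it passed in 10 of 16 alternatives. The extracellular matrix list was lower, with a median of -0.21 over 23 members and adjusted p = 0.0138 (adjusted p = 0.734 with an estimated correlation). None of its members passed, with Col1a1 at -0.60 and Col3a1 at -0.48. These 2 were not lower on TAC A, where Col1a1 was 7.33, within the sham range, and Col3a1 11.15, above every sham array. Without TAC A the matrix median was -0.29 (camera adjusted p = 5.09e-06). The matrix call was lost without TAC C (median -0.09, adjusted p = 0.389), with no floor (adjusted p = 0.486) and with the muscle score as a covariate (median -0.10, adjusted p = 0.198). The count of lists was 7 without TAC A and 7 without sham C and TAC B. Of the 9 other splits of the 6 arrays into groups of 3, 7 gave more than 4 lists.

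Single members passed in lists that camera did not call with all arrays. Their list-alone p does not account for the number of lists searched, and over all probe sets limma gave an adjusted p of 0.512 for both Egr1 and Calr. Camera called the unfolded protein response list without TAC B and the immediate-early list without sham C and TAC B. The immediate-early transcription factor Egr1 fell from 10.38 ± 0.44 to 9.02 ± 0.35 (SD, n = 3), or 2.58-fold, with list-alone adjusted p = 0.0359. Its list had 10 members higher and 10 lower, with a median of 0.03 and a mean of 0.0061. The camera direction was down (adjusted p = 0.831). Next by p in that list were Dusp1 at 0.60, Per1 at 0.58 and Btg2 at 0.47, which were higher and did not pass. A second Btg2 probe set was at -0.01. The endoplasmic reticulum chaperone calreticulin (Calr) fell by 0.45 on the log2 scale (list-alone adjusted p = 0.0421). Egr1 did not pass without sham A, sham B, TAC B or TAC C (list-alone adjusted p = 0.134 to 0.182), and among single arrays left out Calr passed only without sham B (list-alone adjusted p up to 0.200 without the others). Over all alternatives Egr1 passed in 8 of 16, and not with no floor, array weights, the block or the muscle score. Calr passed in 5 of 16, and not with quantile normalization, the mean of all probe sets, the block, either covariate score or without sham C and TAC B (list-alone adjusted p up to 0.250). In the adrenal chromaffin list, too short to test with 4 measured members, with a median of 0.31, Chgb and Slc18a1 rose (list-alone adjusted p = 0.00490 for both). These are the same probe sets already counted in the neuropeptide and catecholamine lists. Over the longer catecholamine list Slc18a1 had a list-alone adjusted p of 0.0367. The other chromaffin members, Chga at 0.15 and Pnmt at 0.02, did not pass.

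No marker list of a cell type of the ganglion was called by camera or fry with all arrays and equal weights. Camera called the fibroblast list with array weights, the fibroblast and satellite glia lists without TAC A, and the macrophage list without sham C and TAC B. The sympathetic neuron list had a median of -0.03 over 19 members, with 0 changed, and among them Insm1 was at -0.94 and Eno2 at 0.14. Satellite glia had a median of -0.15 over 11 members, fibroblasts -0.14 over 12, macrophages -0.10 over 13, endothelium 0.06 over 7 and mural cells 0.31 over 6. The nerve injury list had a median of -0.04 over 19 members and a mean of 0.10. The cholinergic and gp130 cytokine list had a median of 0.11 over 8, the ion channel list -0.02 over 27 with a mean of 0.0040, the receptor list -0.07 over 18 and the neurotrophic factor list -0.05 over 12.

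Medians of further uncalled lists were 0.12 for inflammation over 6 members, -0.07 for interferon over 20, -0.02 for the respiratory chain over 32 and -0.02 for the unfolded protein response over 20, whose mean was 0.02. They were -0.0046 for oxidative stress over 16, with a mean of 0.10, 0.04 for cholesterol and fatty acid synthesis over 21, 0.25 for glucocorticoid-regulated genes over 14 and 0.07 for the cell cycle over 7. Camera called the glucocorticoid list with no floor, without TAC A and without TAC C. Lists with under 5 measured members were not tested. Their medians were 0.02 for myelinating Schwann cells, with a mean of -0.01, -0.82 for red blood cells and 0.04 for sensory neurons, with 0 measured members for T cells and for neutrophils and 1 member each for B cells at -0.0025, mast cells at -0.09 and cartilage at 0.48.

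Skeletal muscle and fat transcripts differed strongly between arrays of the same group. The fast myosin gene Myh4 spanned 5.62 on the log2 scale and measured 7.25, 2.65 and 8.17 on sham A, B and C and 6.45, 3.49 and 2.55 on TAC A, B and C. Ucp1, the uncoupling protein of brown fat, measured 8.54 on sham C and 6.82 on TAC B, against at most 4.64 on the other arrays. The median TAC minus sham difference was -1.86 for the skeletal muscle list over 7 members, -0.62 for white fat over 5 and -0.53 for brown fat over 5, and none of the 3 lists was called with all arrays and equal weights. Camera called the muscle and white fat lists with array weights and without sham B, and the white fat list without TAC B and without sham C and TAC B.

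**Figure D3:**
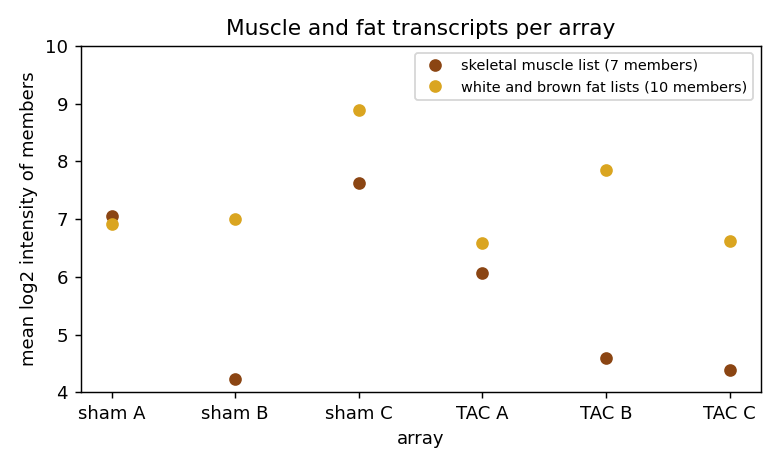
The y axis gives the mean log2 intensity of the measured members of the skeletal muscle list and of the combined fat lists on each of the 6 arrays. Muscle transcripts were high on sham A, sham C and TAC A, at 7.05, 7.63 and 6.07, and fat transcripts on sham C and TAC B, at 8.89 and 7.85.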

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

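The covariate scores, the comparison without sham C and TAC B, and the results on the neuropeptide, matrix, heat shock and clock lists were added after the data had been seen; the cause of the changes below was not tested unless stated. Probe sets called stayed at 0 except for 110 (85 higher, 25 lower) with an unadjusted p under 0.01 and a log2 difference of at least 0.58, and 0 to 1 with 1 array left out (1 without TAC C, Sst). Lists called numbered 4 with the main settings, 0 with an estimated correlation, 7 with array weights, 2 with the muscle score and 7 without sham C and TAC B. They numbered 5 with no floor and with the mean of all probe sets, and 3 with a floor of 6, quantile normalization and the block. With no floor the 5 were the catecholamine, neuropeptide, synaptic vesicle, glucocorticoid and clock lists. With 1 array left out the count was 3 to 7. The neuropeptide median kept its direction in each alternative, at 0.438 to 0.531 with 1 array left out, and its camera call was lost with an estimated correlation (median 0.464, adjusted p = 0.188). Its count of members, 9, was 5 with no floor, where more dim members enter, 5 with the muscle score and 4 to 10 with 1 array left out. The neuropeptide count was 8 with a floor of 6, 10 with trend and robust and 8 without sham C and TAC B. Camera called the catecholamine list with no floor (median 0.025, adjusted p = 0.0309) and in no other alternative, with a median of 0.020 to 0.052 with 1 array left out; fry called it with all arrays (adjusted p = 0.0144). Its count of members, 1, was 2 with no floor and 2 with trend and robust, where Th passed too, and 0 with array weights, quantile normalization, the brown fat score, without sham C and TAC B, and 0 to 1 with 1 array left out. The letters A, B and C did not pair the arrays: deviations from the group means correlated at 0.084, -0.003 and -0.166, and no sham array correlated best with its own letter. With the letter as a block, 0 probe sets and 3 lists were called, the catecholamine count was 0 and the neuropeptide count 9.

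Depth here is signal over background. With no floor, 7642 probe sets had an unadjusted p under 0.05, and 87.0% of the 27487 probe sets under the floor were lower on the TAC arrays, with a median difference of -0.04 on the log2 scale. Fitted on their own by limma, 14054 of these dim probe sets had an unadjusted p under 0.05, 13973 of them lower in TAC. Whether the processing caused this was not tested, and it limits the comparison for values near the floor. With a floor of 6, Sst was not tested. Of 2801 gene values under alternatives, 2642 kept direction and side of the threshold, 59 lost the call, 54 gained it and 46 changed sign. Most of these values belong to genes that had not passed with the main settings and so had no call to lose. The counts therefore do not measure how stable the calls were, which the tallies for single genes in the Results show. Each sign change was in a gene that had not passed. With array weights Dbh was -0.0081, Ddc 0.012 and Pcsk1n 0.010. With quantile normalization Pnmt was -0.054. With the mean of all probe sets Gch1 was 0.109, Ndufs4 -0.054, Drp2 -0.0062 and Ighm 0.142. With the brown fat score Ighm was 0.0022 and Cidea 0.035. With the muscle score Pcbd1 was 0.018, Pnmt -0.0076, Mal 0.029 and Ighm 0.0048. Without sham C and TAC B, Pcbd1 was 0.095, Socs3 -0.138, Cdkn1a -0.095, Pcna -0.076, Mal 0.070, Ighm 0.0070 and Kit 0.0025. With 1 array left out, ranges that crossed 0 were -0.022 to 0.064 for Dbh, -0.049 to 0.051 for Pnmt, -0.090 to 0.358 for Drp2, -0.229 to 0.030 for Hbb-b2, -0.084 to 0.049 for Pcbd1, -0.017 to 0.011 for Ighm, -1.40 to 0.069 for Adipoq, -0.619 to 0.122 for Dgat2, -0.572 to 0.118 for Cidea, -0.057 to 0.0091 for Ddc, -0.024 to 0.225 for Calcb, -0.032 to 0.558 for Socs3, -0.057 to 0.209 for Sdha, -0.068 to 1.22 for Cdkn1a, -0.015 to 0.199 for Pcna, -0.181 to 0.060 for Mal and -0.0065 to 0.046 for Cyb561.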

Other observations

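The tests of neuronal share, dilution by muscle, carry-over of muscle and fat, the operation and time of day were chosen after the results they bear on had been seen. The matched random lists and the other splits of the arrays were chosen before. Their use on the neuropeptide list is not independent of its result, as results on that list were added after the data had been seen. The synaptic vesicle list, with 22 measured members, had members on both sides. Its median log2 difference was 0.10, with 15 members higher and 7 lower, and 0 passed over the list alone. Fry for change in either direction gave adjusted p = 0.0204, and for a shift one way adjusted p = 0.351. Camera did not call the list (adjusted p = 0.244), except with no floor and with the mean of all probe sets of a gene. Higher means were measured for Vamp1 at 0.35, Syt5 at 0.35, Napb at 0.28 and Snap25 at 0.23. Members chosen after their values were seen, Doc2b at -0.29 and Cplx2 at -0.25, were lower.

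The rise of neuropeptide and granin transcripts may have a technical origin. A larger neuronal share of the TAC samples would lift all neuronal transcripts alike, but the sympathetic neuron list had a median of -0.0271, below the neuropeptide median of 0.464. Its 95% bootstrap interval was -0.064 to 0.054. The bootstrap drew list members and not animals, so the interval leaves out variation between animals. Against an intensity-dependent normalization difference, the neuropeptide median lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.189. Dilution of the sham samples by skeletal muscle also fell short, since the median with the muscle score as a covariate was 0.444, although the count of members past the list-alone threshold went from 9 to 5. These tests argue against each of the 3 as the whole cause. A response of the ganglion to pressure overload stays a hypothesis. A change in the mix of neuron types, differences between the operations and the time of day at dissection were not tested for these transcripts. Nor was a batch of arrays that coincides with the groups, which the matched random lists do not address. Median linear intensities of the groups did not overlap, at 7.96 to 8.44 for sham and 7.81 to 7.85 for TAC arrays.

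The 10 splits of 6 arrays are too few to give a share under 0.05. Each of the 9 others sets 2 sham and 1 TAC array against 1 sham and 2 TAC arrays. A part of any real group difference remains in them, so they are neither free of it nor independent of the real split. The neuropeptide list had 9 members past the list-alone threshold in the real split and at most 0 in the others (1 of 10 splits), and a median of 0.464 against at most 0.30 in size (1 of 10), though camera called it in 4 of the 9 others. Probe sets at an unadjusted p under 0.05 numbered 1594 against at most 969 (1 of 10). The number of lists called, 4, was reached or passed in 9 of 10 splits including the real one, with up to 9 in another, and the cause was not tested. The catecholamine median of 0.03 was reached in 2 of 10, with 0.04 the highest other, and its count of 1 in 1 of 10, with 0 the highest other. Probe sets called numbered 0 in all 10 of 10 splits.

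Skeletal muscle and fat may have been carried over with the ganglia in differing amounts. If so, the members of each list should move together between arrays. The SD over arrays of the list mean lay at percentile 100 of 10000 draws that shuffled each member over the arrays. It was 1.47 for muscle, against at most 1.39, and 0.90 for fat, against at most 0.674. Shuffling breaks any shared variation, whatever its source, so this shows that members moved together and cannot single out carry-over at dissection. Acta1 reached 9.18 and Myh4 8.17 on sham C, and Fabp4 12.63. Myl1, Tnnc1 and Fabp3 of these lists spanned only 0.63, 0.38 and 0.66 between arrays. The values argue against the operation as the whole source, since arrays of the same operation differed: the SD within groups lay at percentile 100 of matched random lists for both (1.44 for muscle and 0.94 for fat, against at most 0.732 and 0.396), while a part of it in the difference between groups stays open (exact two-sided permutation p of the mean over the 17 members 0.4, the smallest possible 0.1).

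The clock transcripts may reflect the time of day at dissection, which the labels do not give. Per1, Per3, Cry1, Cry2, Dbp and Nr1d2 are targets of the Arntl and Clock proteins, and the mean of these 6 less that of Arntl and Clock was 0.528 higher in TAC on the log2 scale. The exact two-sided permutation p was 0.1, the smallest 3 animals a group can give, and a time difference between groups cannot be told apart from an effect of TAC.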
